A study of Mus musculus with 6 samples.

How the data were processed

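Single-cell RNA sequencing was done on embryoid bodies at day 6 of motor neuron differentiation of HB9::GFP mouse embryonic stem cells, in 6 libraries: 2 WT, 2 DeltaSP and 2 KO, each from a separate clone per the series labels. The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 4.0 on mm10 and Ensembl release 93, with no normalization. The labels name the 10x 3' kit in more than 1 version. Each deposited barcode held at least 500 UMIs, and totals ran from 24191242 to 49061693 UMIs per library. Of 31053 gene names, 30477 matched a gene of the GENCODE annotation, 30464 had a transcript length and 21595 an annotated 3' UTR.

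Cells were kept with at least 1000 genes and at most 10% mitochondrial UMIs, which left 16225. Scrublet as implemented in scanpy 1.11.5 then marked 74 doublets, 0.456% of them, far below the expected 6%, so it did not work as a doublet filter, and 16151 cells were kept. Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering (leidenalg 0.10.2) at resolution 0.6, without integration of the libraries. Clusters were named from marker lists fixed before the files were opened; the rules for how many markers a name needs were changed after the clusters were seen. Progenitor-like cells are clusters named neural progenitor or p3 or floor plate, and neuron-like cells those named motor neuron or interneuron; no cluster was named motor neuron progenitor. Clusters of committing precursors, of other types and without a name stayed in the all-cell sums and out of both classes.

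UMIs were summed per library over all cells, progenitor-like cells or neuron-like cells. CPM in the comparisons are scaled by TMM; those of single clusters, of T lymphocyte genes and in the observations are plain, over the total of the library or cluster. Genes were tested in edgeR 4.0.16 (R 4.3.3) with TMM, filterByExpr, the quasi-likelihood test and Benjamini-Hochberg adjustment, threshold 0.05, with the 6 libraries in 1 fit and genotype as its term. Each library is 1 clone, so p values measure the spread between libraries, in which clone, library preparation and depth are not separated. In each of 3 cell sets, 3 comparisons were made. The effect in neuron-like against progenitor-like cells was tested with library as a block. Of 35 lists, those with 3 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it: neural progenitor, motor neuron progenitor, p3 or floor plate, committing neuronal precursor, motor neuron, pan-neuronal, interneuron, pluripotent, endoderm, mesoderm, endothelial, neural crest, surface epithelium, glial, blood, S phase, G2 and M phase, Notch, hedgehog, retinoic acid, Hox 1 to 5, Hox 6 to 10, axon guidance, synaptic, neurofilament, p53, hypoxia, endoplasmic reticulum stress, immediate early, imprinted, cholesterol, Y chromosome, locus, mitochondrial and ribosomal genes. Shares of cells were compared with a two-sided exact permutation test over libraries, and also with edgeR on the cell counts per class, adjusted over the classes. Sets of genes with micro RNA sites in the 3' UTR were tested with camera; the sites were derived from the mature sequences as known to the analyst, without a reference file of them. The overlap of both edits was set against 20 simulations of unchanged groups, with the same and with different WT libraries and each gene drawn independently.

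Design, lists, tests and the rule for named genes were fixed before the data were examined. By that rule the text names, per comparison, up to 8 of the largest rises and 8 of the largest falls among passing genes with non-overlapping libraries and a mean of at least 20 CPM in the higher genotype, up to 4 members of each list with the smallest p, the targeted transcript, and Sox2, Olig2, Neurog2, Mnx1, Isl1, Lhx3, Chat, Tubb3 and Mki67 throughout; where fewer than 5 genes pass, the 5 with the smallest p are named as not passing. From these, genes that bear on a described group were taken; some that the rule takes are not reported here. Interferon-induced, T lymphocyte and neutrophil genes, H19 and the single Y-linked genes were chosen after the data were seen.

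The test was checked on simulated data with 100 genes changed 2-fold and 100 changed 4-fold: over all cells it recovered 59% and 99% with 17 false calls, in progenitor-like cells 56% and 96% with 10, and in neuron-like cells 48% and 98% with 13. Alternatives planned beforehand were DESeq2 size factors, no filter on low counts, a replicate block, leaving out each library, a looser cell filter (500 genes, 20% mitochondrial UMIs), doublets kept, resolution 1.2, thinning (of cells to 3000 UMIs, with cells below left out, 14654 staying, or of sums to the smallest library), fits with only the genotypes compared, and the DESeq2 1.42.0 Wald test, in which independent filtering was switched off after it was seen to leave the targeted transcript without an adjusted p. Removing the 6% of cells with the highest doublet scores, removing the trend with transcript length and counting neuronal cells without clusters were added after seeing the data. A floor of 3 UMIs per library stands for a count of 0, and floors cover counting error only. Outlier tests and other splits of the samples need larger groups and were not made. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.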

Results

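Embryoid bodies grown from HB9::GFP mouse embryonic stem cells, a line in which a green fluorescent reporter marks motor neurons, were profiled by droplet RNA sequencing at day 6 of motor neuron differentiation. The 6 libraries came from wild-type cells (WT) and from cells edited with CRISPR/Cas9 at the lncMN2 locus, named DeltaSP and KO in the labels, with 2 libraries of separate clones per genotype. The deposited counts held 24215 barcodes and 201615681 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule). Library totals were 24191242 and 27883163 UMIs in WT 1 and WT 2, 37494787 and 49061693 in DeltaSP 1 and DeltaSP 2, and 30900060 and 32084736 in KO 1 and KO 2. After filtering, 4496 and 1591 WT cells, 2255 and 3598 DeltaSP cells and 2119 and 2092 KO cells remained. WT 1 stood apart in depth, with a median of 4156 UMIs per kept cell against 11896.5 to 15051 in the other libraries. All errors below are SD over n = 2 libraries for levels and shares, and SE of the fit for log2 fold changes.

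The first question was what each edit left of the targeted transcript. The long non-coding RNA 5330434G04Rik (ENSMUSG00000087620; mm10 chromosome X, 105348282 to 105391776, minus strand), whose annotated span contains Mir325, reached 36.1 ± 1.71 CPM (UMIs of a gene scaled to a common library total, corrected by TMM except where plain CPM are named) in WT, 22.9 ± 0.55 in DeltaSP and 0.149 ± 0.033 in KO. In WT it was more abundant in neuron-like cells, at 65.3 and 57.9 CPM, than in progenitor-like cells, at 16.4 and 20.3 CPM. In KO against WT its log2 fold change was -7.88 ± 0.23, a 235-fold lower level with adjusted p = 3.18e-05 in edgeR, and between -7.67 and -8.11 when any of the libraries was left out. KO 1 and KO 2 held 4 and 6 UMIs of it, so the size of this fold rests on few UMIs. DeltaSP differed from WT by -0.65 ± 0.14 with adjusted p = 0.152, which did not pass. Tags at the 3' end count a transcript without showing which part of it is missing, so the level in DeltaSP does not check that edit.

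The second question was which cell types formed. Neuron-like cells made up 38.7% ± 1.64 of the kept cells in WT, 27.5% ± 6.25 in DeltaSP and 22.5% ± 0.97 in KO, and motor neuron-like cells, the larger part of them, 31.7% ± 6.58, 22.5% ± 5.01 and 18.0% ± 1.18. Progenitor-like cells made up 28.8% ± 1.99 in WT, 33.7% ± 2.26 in DeltaSP and 40.7% ± 7.99 in KO. Committing precursor-like cells took 15.04% ± 5.62, 17.3% ± 0.97 and 18.6% ± 1.14, and mesoderm-like cells 1.79% ± 0.31, 3.88% ± 0.29 and 2.42% ± 1.12. Unnamed clusters held 15.7% ± 1.69, 17.6% ± 4.67 and 15.8% ± 4.76. Among neuron-like cells the motor neuron-like part was 81.8% ± 13.5 in WT, 81.9% ± 0.37 in DeltaSP and 79.8% ± 1.80 in KO.

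The difference between KO and WT was -16.2 percentage points for neuron-like cells, -13.7 for motor neuron-like cells and 11.8 for progenitor-like cells, and in this clustering both KO libraries lay on the same side of both WT libraries in each. DeltaSP and WT differed by -11.2, -9.21 and 4.87 points, with libraries that did not overlap in this clustering either. The progenitor-like class included a cluster led by the interferon-induced Oasl2, with 4.04% and 1.92% of kept cells in DeltaSP. It held 0.142% and 0.717% in KO and 0% in both WT libraries. Progenitor-like cells made up 32.1% in DeltaSP 1 and 30.2% in WT 2, a gap smaller than that 4.04%. With that cluster counted outside the class, DeltaSP and WT libraries would overlap in progenitor-like cells. The looser cell filter and thinning to 3000 UMIs before clustering, which left out the cells below that depth (936 of WT 1 and 56 to 201 of each other library), brought the KO minus WT difference to -7.46 and -10.2 points for neuron-like cells and -5.57 and -7.59 for motor neuron-like cells, where KO 1 (23.5% and 24.2%) lay above WT 1 (21.9% and 21.7%). DeltaSP minus WT became -2.68 and -4.13 for neuron-like cells and -0.997 and -2.51 for motor neuron-like cells, with DeltaSP 1 above WT 1 in both (34.8% against 31.1% and 37.3% against 31.9% of neuron-like cells). Under the looser filter, unnamed clusters held 19.2% and 13.8% of the WT cells, against 5.33% to 8.16% of each DeltaSP and KO library. After thinning they held 19.9% of WT 1 and 0.696% to 3.49% of each other library. Unnamed cells count in the totals, so the smaller differences are not separated from the naming of clusters. For progenitor-like cells the looser filter gave 8.98 points for DeltaSP minus WT and 4.22 for KO minus DeltaSP. A two-sided exact permutation test gave p = 0.333 for these 6 differences, the smallest p that 2 libraries against 2 allow, so none could reach 0.05. The planned edgeR test of cell counts per class, which could reach it, gave adjusted p = 0.083, 0.287 and 0.259 for neuron-like, motor neuron-like and progenitor-like cells in KO against WT, 0.265, 0.425 and 0.548 in DeltaSP against WT, and 0.598, 0.778 and 0.598 in KO against DeltaSP, and 0 passed. KO and DeltaSP differed by -4.98 points in neuron-like cells (exact p = 0.667), -4.53 in motor neuron-like cells (exact p = 0.333) and 6.97 in progenitor-like cells (exact p = 0.667). Leaving out DeltaSP 1 or DeltaSP 2 moved the first of these to -0.56 or -9.40 and the second to -0.99 or -8.08. For progenitor-like cells, KO minus DeltaSP was 12.6 without KO 1 and 1.31 without KO 2, and KO minus WT was 6.19 without KO 2. DeltaSP minus WT in neuron-like cells was -6.76 without DeltaSP 2, in motor neuron-like cells -13.9 without WT 1, -4.56 without WT 2 and -5.67 without DeltaSP 2, and in motor neuron-like cells KO minus WT was -9.10 without WT 2. Counted without clusters, cells with at least 10 UMIs of pan-neuronal genes after thinning to 3000 UMIs, with the same cells left out, made up 45.1% ± 3.48 in WT, 32.0% ± 6.61 in DeltaSP and 25.5% ± 2.04 in KO. WT 1 filled clusters of its own within the classes: it gave 848 of 904 cells in a precursor-like cluster, 878 of 1047 in a motor neuron-like cluster and 1079 of 1120 in a progenitor-like cluster.

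**Figure D1:**
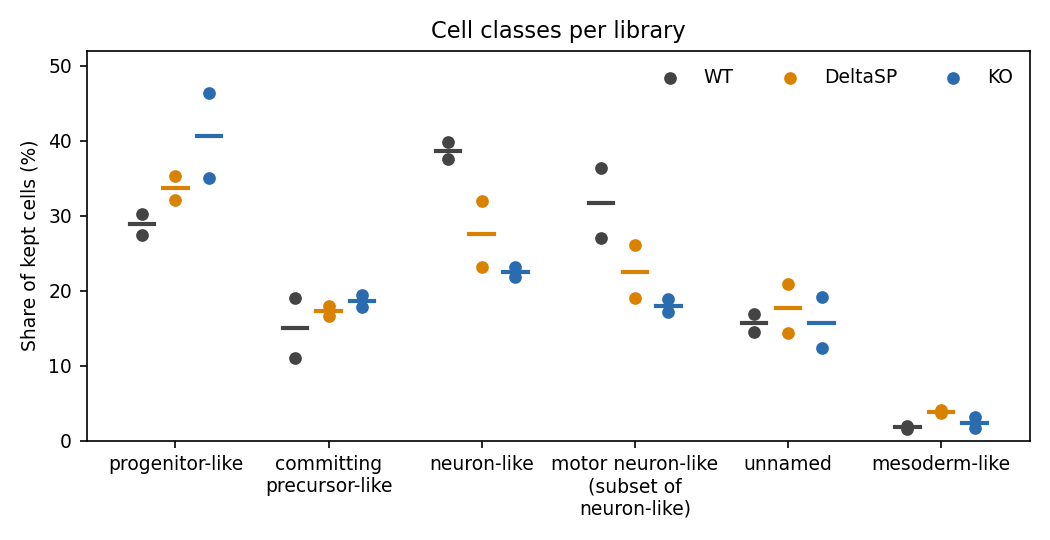
Share of kept cells (%, vertical axis) in each cell class (horizontal axis); points are libraries and lines are means of the 2 libraries of a genotype. Neuron-like cells averaged 38.7% in WT, 27.5% in DeltaSP and 22.5% in KO.

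KO against WT asked how expression differed where the targeted transcript was nearly absent. Summed over all cells, genes of neuronal structure fell in KO: Stmn2, which regulates microtubules in growing axons, went from 1595 ± 51.1 to 698 ± 196 CPM (log2 fold change -1.19 ± 0.25), and Dcx, a microtubule protein of young neurons, from 189 ± 7.68 to 69.1 ± 10.4 CPM (-1.45 ± 0.20). Cell cycle genes rose, with the proliferation marker Mki67 going from 43.1 ± 5.04 to 92.96 ± 16.2 CPM (1.11 ± 0.17), and so did Olig2, the motor neuron progenitor factor, from 172 ± 9.42 to 297 ± 6.82 CPM (0.79 ± 0.14). Of 15 tested pan-neuronal genes 8 fell (13 adjusted over the list alone), among them Mapt (-1.22) and Stmn3 (-1.34). Of 20 synaptic and transmitter genes 6 fell (10 adjusted over the list alone), with Syt1 at -1.53 and Chat, which makes acetylcholine, at -0.75. Of 18 neurofilament and cytoskeleton genes 5 fell (15 adjusted over the list alone), with Tuba1a at -1.75. Of 22 axon guidance and adhesion genes 2 fell (7 adjusted over the list alone), the ephrin receptor Epha5 at -2.90 (-2.16 without WT 1) and L1cam at -1.53. Among S phase genes 15 of 43 rose (30 adjusted over the list alone), with Pcna at 1.18 and Cdc6 at 1.27, and the thymidine kinase gene Tk1 rose by 1.40. Among G2 and M phase genes 18 of 51 rose (36 adjusted over the list alone), with Aurkb at 1.32 and Cdk1 at 0.88. Motor neuron progenitor genes rose in 2 of 4 (2 adjusted over the list alone), Olig2 and Olig1 (0.93). The share of neuron-like cells was lower, and that of progenitor-like cells higher, in these KO libraries than in the WT libraries. Of the motor neuron factors, Mnx1 (-0.38), Isl1 (-0.46) and Lhx3 (0.06) did not pass, nor did Tubb3 (-0.57), Sox2 (0.63) or Neurog2 (0.34).

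In the same comparison, a few imprinted and Hox genes changed. Cdkn1c, an imprinted inhibitor of the cell cycle, went from 273 ± 1.68 to 30.03 ± 6.15 CPM (-3.18 ± 0.19), and the growth regulator Grb10 fell by 2.80 on the log2 scale. Of 24 imprinted genes 2 fell and 1 rose, Mest at 0.94 (5 and 3 adjusted over the list alone). Hox genes, which set position along the body axis, fell in 1 of 15 of paralogues 1 to 5, Hoxa5 at -2.13 (-2.72 without KO 1; 2 adjusted over the list alone), and in 1 of 10 of paralogues 6 to 10, Hoxb9 at -2.18 (4 adjusted over the list alone); the antisense transcript Hoxb5os fell by 3.71 (-4.66 without KO 1, -3.12 without KO 2). The non-coding Gm2694 fell by 3.72. Of 97 ribosomal protein genes 27 fell (51 and 2 rising adjusted over the list alone), with Rps29 at -2.60 and Rps27 at -2.23, and of 13 mitochondrially encoded genes 2 fell (2 adjusted over the list alone), with mt-Nd3 at -3.05. The 1476 genes with the shortest transcripts, up to 1281 bases, had a median of -0.39, and within WT the same genes were higher in WT 1 than in WT 2 by a median of 0.24. Other list members past the threshold were Sox3 (1.11) and Ptn (-1.19) among neural progenitor genes, Dll1 (0.80) and Neurod4 (0.62) among committing precursor genes, and Junb (-1.34) and Jun (-0.95) among immediate early genes. Single members passed in further lists: Ccng1 at 0.95 in the p53 response, Gli3 at 1.12 in the hedgehog response, and Slc2a1 at 1.05 and Mif at -1.31 in hypoxia and glycolysis. Cox7b, a respiratory chain gene near the edited locus, fell by 1.68. The interferon-induced genes Bst2 (1.99; 1.39 without KO 2) and Trim25 (1.86) rose, as did Cd2, a surface protein of T lymphocytes, from 0.142 ± 0.20 to 66.7 ± 0.60 CPM.

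Over all tested genes the KO and WT libraries did not overlap for 59.3%. Chance alone separates 33.3% on average, but genes are not independent, so this share is not a test. It was 47.9% between DeltaSP and WT and 41.8% between KO and DeltaSP, where 1 gene passed. In all, 1073 of 14872 tested genes passed in KO against WT by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 399 higher and 674 lower in KO. The count was 260 without WT 1, 3240 without WT 2, 672 without DeltaSP 1, 684 without DeltaSP 2, 32 without KO 1 and 4 without KO 2. Of the 42 genes named above as passing, with adjusted p from 3.18e-05 (5330434G04Rik) to 0.0492 (Mest), 14 still passed without WT 1, 42 without WT 2, 34 without DeltaSP 1, 34 without DeltaSP 2, 7 without KO 1 and 3 without KO 2. By camera with a preset correlation of 0.01, 12 of the 34 lists passed in KO against WT. The lists for motor neuron progenitor (adjusted p = 0.0208), S phase (adjusted p = 6.68e-13) and G2 and M phase (adjusted p = 1.63e-14) were higher. The pan-neuronal (adjusted p = 8.89e-10), neurofilament (adjusted p = 5.69e-09), synaptic (adjusted p = 4.28e-07), axon guidance (adjusted p = 0.012), Hox 1 to 5 (adjusted p = 0.0425), Hox 6 to 10 (adjusted p = 0.00439), mitochondrial (adjusted p = 0.0425), ribosomal (adjusted p = 6.66e-14) and locus lists (adjusted p = 0.0294) were lower. None of these calls held when the correlation between genes was estimated, where the 12 lists had adjusted p = 0.543 to adjusted p = 0.569 with an estimated correlation and 0 of 34 reached an unadjusted p under 0.05. The other lists, with adjusted p from 0.0504 to 0.962 by camera, covered neural progenitor, p3 or floor plate, committing precursor, motor neuron, interneuron, pluripotent, endoderm, mesoderm, endothelial, neural crest, surface epithelium, glial, Notch, hedgehog, retinoic acid, p53, hypoxia, endoplasmic reticulum stress, immediate early, imprinted, cholesterol and Y chromosome genes. The blood list had too few tested members. The list median, mean and test differed in sign for the neural progenitor, mesoderm, retinoic acid, immediate early and locus lists, the last with a median of 0.14, a mean of -0.65 and a lower call. The locus list includes the targeted transcript itself, at -7.88, so its lower call does not show a change of the neighbours.

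**Figure D2:**
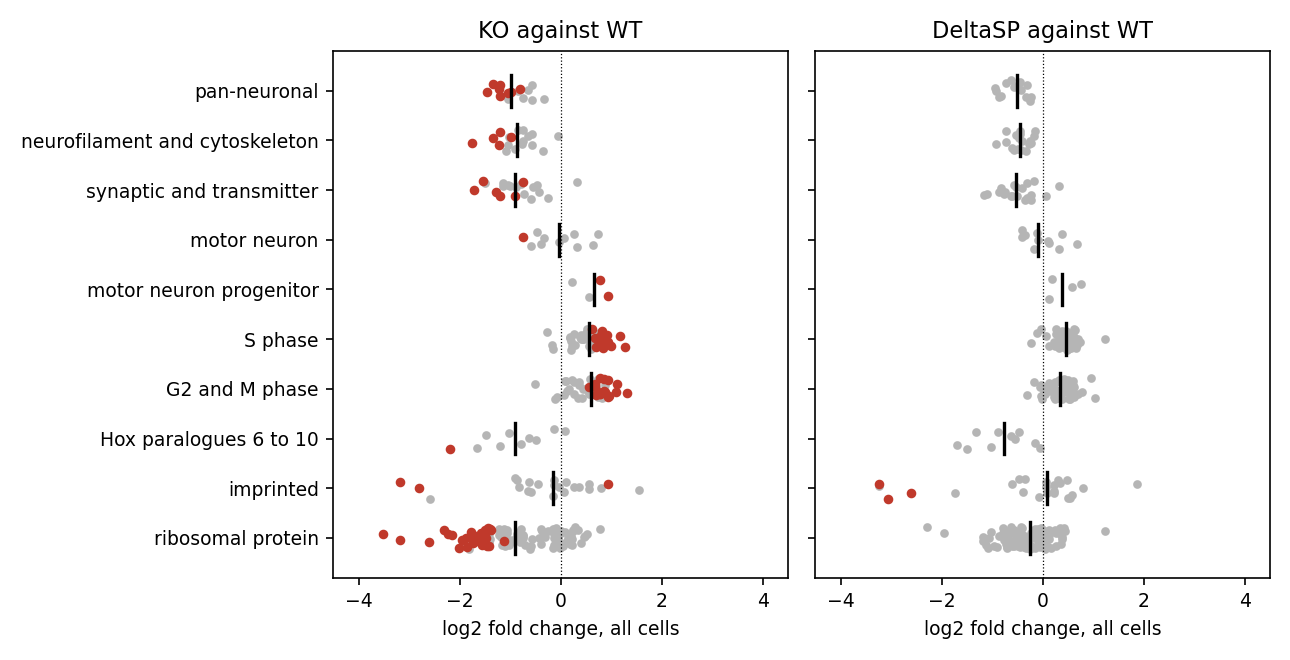
Log2 fold change over all cells (horizontal axis) of the members of 10 gene lists (vertical axis) in KO and DeltaSP against WT. Red points passed the edgeR test, grey points did not, and black bars are list medians. The pan-neuronal median was -0.98 in KO and -0.51 in DeltaSP.

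Within progenitor-like cells, single genes of several lists fell in KO. Tubb3, the neuronal tubulin, went from 152 ± 43.7 to 62.8 ± 2.98 CPM (-1.27 ± 0.20), the neurofilament Nefl fell by 1.63 and Epha5 by 3.03. Of the progenitor-like cells of WT 1, 87.5% lay in 1 cluster, which held at most 2.29% of those of any other library. The class was thus not made of the same clusters in each genotype. The Hox cluster transcript Hotairm1 went from 379 ± 19.03 to 48.8 ± 26.2 CPM (-2.96 ± 0.35; -3.64 without KO 1), Grb10 fell by 3.56 (-4.44 without KO 1, -2.96 without KO 2) and Cdkn1c by 3.33. Olig1 (0.94), Ccng1 (0.96), Cdc6 (0.91) and Tk1 rose, and the ribosomal gene Rps29 fell by 2.76. In all 181 of 12570 genes passed in edgeR, 13 higher and 168 lower in KO. The count was 98 without WT 1, 2257 without WT 2, 2 without KO 1 and 0 without KO 2. It was 3 when the trend with transcript length was removed, where Tubb3 stood at -1.37 and Rps29 at -1.41, neither passing. Of the 12 genes named as passing, 9 still passed without WT 1, 6 without DeltaSP 1, 6 without DeltaSP 2, 2 without KO 1 and 0 without KO 2. By camera 13 of 29 lists passed, 5 higher and 8 lower. Pan-neuronal genes fell in 2 of 15 (14 adjusted over the list alone; camera adjusted p = 2.44e-13) and had adjusted p = 0.46 with an estimated correlation, the lowest value of any list and shared by 9 of them. Of the genes named in every comparison, those other than Tubb3 did not pass and lay between Isl1 at -0.78 and Mki67 at 0.57.

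Within neuron-like cells, the motor neuron factors did not pass between KO and WT. Mnx1, the gene whose regulatory sequence drives the reporter, stood at 212 ± 1.86 CPM in WT and 215 ± 31.1 in KO (0.02 ± 0.17, adjusted p = 0.953 in edgeR), and Isl1 (-0.14), Lhx3 (0.15), Chat (0.01), Tubb3 (0.09), Sox2 (1.22), Olig2 (0.97), Mki67 (0.89) and Neurog2 (-0.15) did not pass either. Cyp26b1, which degrades retinoic acid, went from 52.5 ± 27.7 to 2.04 ± 2.09 CPM (-4.66 ± 0.75; not passing without WT 1, without KO 1, at -6.50, or without KO 2, at -3.88), and the secreted growth factor Ptn from 329 ± 56.4 to 75.3 ± 17.7 CPM (-2.13 ± 0.23). Dcx (-0.79), Syt1 (-0.98), Tuba1a (-1.30), Junb (-1.72), Hoxb9 (-2.67) and Cdkn1c (-2.67) fell. Dll3 (1.14), a Notch ligand of differentiating cells, Slit3 (0.79), a secreted axon guidance factor, Btbd17 (1.61) and Cldn3 (1.71) rose. Cd2 had 0 UMIs in the neuron-like cells of both WT libraries and was at least 246-fold higher in KO, taking 3 UMIs per library as the floor. In all 503 of 12855 genes passed in edgeR, 138 higher and 365 lower in KO. The count was 40 without WT 1, 2020 without WT 2, 4 without KO 1 and 3 without KO 2. Of the 14 genes named as passing, 5 still passed without WT 1, 11 without DeltaSP 1, 11 without DeltaSP 2, 2 without KO 1 and 3 without KO 2. By camera 14 of 29 lists passed, 7 higher and 7 lower, with ribosomal genes (25 of 95 falling, 51 adjusted over the list alone) at adjusted p = 1.42e-20 and motor neuron genes (1 of 11 rising, 3 adjusted over the list alone) at adjusted p = 0.0148. The lowest value of any list was adjusted p = 0.655 with an estimated correlation. The locus list, which passed and includes the targeted transcript, differed in sign between median and mean.

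DeltaSP against WT asked how the other edit differed from unedited cells. The rises included interferon-induced genes, a group chosen after the data were seen: Isg15, a ubiquitin-like protein induced by interferon, went from 3.03 ± 1.17 to 65.0 ± 8.16 CPM (4.45 ± 0.53), and Rtp4 (6.40), Oasl2 (5.64), Usp18 (5.58), Rnf213 (3.99), Bst2 (3.42) and Trim25 (2.43) rose too. Cd2 rose from 0.142 ± 0.20 to 66.5 ± 4.71 CPM. The imprinted genes Cdkn1c (273 ± 1.68 to 32.5 ± 3.78 CPM, -3.07 ± 0.19), Dlk1 (116 ± 51.0 to 12.4 ± 3.07 CPM, -3.23 ± 0.33) and Grb10 (-2.61) fell, as did Gm2694 (-2.24), mt-Nd3 (-1.86) and the zinc finger gene Tshz2 (-1.37). Dcx (-0.93), Olig2 (0.58), Mki67 (0.62), Sox2 (0.43), Neurog2 (0.37), Mnx1 (-0.41), Isl1 (-0.34), Lhx3 (0.13), Chat (-0.42) and Tubb3 (-0.32) did not pass. In all 49 of 14872 genes passed in edgeR, 41 higher and 8 lower in DeltaSP. The count was 3 without WT 1, 1174 without WT 2, 1 without DeltaSP 1 and 3 without DeltaSP 2. Of the 14 genes named as passing, 3 still passed without WT 1, 1 without DeltaSP 1, 1 without DeltaSP 2, 12 without KO 1 and 11 without KO 2.

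By camera 14 of 34 lists passed in DeltaSP against WT. Motor neuron progenitor (adjusted p = 0.0337), mesoderm (adjusted p = 0.0169), S phase (adjusted p = 6.4e-12; 20 of 43 rising adjusted over the list alone) and G2 and M phase genes (adjusted p = 2.55e-09) were higher. Pan-neuronal (adjusted p = 9.79e-07; 6 of 15 falling adjusted over the list alone), synaptic, neurofilament, axon guidance, both Hox, immediate early, imprinted, mitochondrial and ribosomal genes were lower, with adjusted p up to 0.0447. With an estimated correlation 0 lists passed by camera, 0 had an unadjusted p under 0.05, and the lowest value was adjusted p = 0.713 with an estimated correlation. The number of lists was 8 without DeltaSP 2. The imprinted list had a median of 0.08 against a mean of -0.39 and a lower call. The median, mean and test also differed in sign for the neural progenitor, motor neuron, neural crest, p53 and locus lists, which did not pass.

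By class, 1 of 12570 genes passed between DeltaSP and WT in progenitor-like cells, Cdkn1c at -3.52 ± 0.23 (101 ± 29.0 to 8.86 ± 0.56 CPM). The smallest p values short of the threshold there were those of Cd2, with 0 UMIs in both WT libraries and at least 10.7-fold higher, and of the interferon-induced Lgals3bp (6.26), Isg15 (8.35) and Bst2 (3.62), all with adjusted p = 0.0968 in edgeR. With WT counts near 0, Lgals3bp was 9.37 and Isg15 12.92 without WT 2, where both passed as they did without KO 1 or KO 2, and 5.61 and 7.64 without WT 1. In neuron-like cells 2 of 12855 genes passed, Cd2, at least 224-fold higher with 3 UMIs per library as the floor, and Cdkn1c (-2.88 ± 0.24). Next to them stood AC158554.1 (1.71), Ifi35 (3.6) and Nxf3 (2.39), which did not pass. The progenitor-like count was 2 without WT 1, 1101 without WT 2, 0 without DeltaSP 1, 2 without DeltaSP 2, 17 without KO 1 and 16 without KO 2, and Cdkn1c did not pass there without either DeltaSP library. The neuron-like count was 1 without WT 1, 746 without WT 2, 13 without KO 1 and 13 without KO 2, and of Cd2 and Cdkn1c 1 passed without WT 1, without DeltaSP 1 and without DeltaSP 2. By camera 14 of 29 lists passed in progenitor-like cells and 6 of 29 in neuron-like cells, the lowest values being adjusted p = 0.531 and adjusted p = 0.944 with an estimated correlation. The imprinted list, which passed as lower in progenitor-like cells, differed in sign between median and mean. The genes named in every comparison did not pass in either class, and lay between Tubb3 at -0.97 and Neurog2 at 0.37 in progenitor-like cells and between Neurog2 at -0.60 and Sox2 at 0.67 in neuron-like cells.

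KO against DeltaSP set the edits side by side. The targeted transcript 5330434G04Rik was lower in KO in all cells (-7.22 ± 0.23, adjusted p = 5.84e-05 in edgeR), in progenitor-like cells (-6.53 ± 0.36, adjusted p = 0.00284) and in neuron-like cells (-7.39 ± 0.29, adjusted p = 0.000126), and was the gene that passed in each, 1 of 14872, 1 of 12570 and 1 of 12855. KO 1 and KO 2 held 1 and 2 UMIs of it in progenitor-like and 2 and 3 in neuron-like cells, so these sizes rest on few UMIs. The next smallest p values in all cells were those of Ifitm3, an interferon-induced membrane protein, at 300 ± 1.83 CPM in DeltaSP and 105 ± 10.6 in KO (-1.51 ± 0.16, adjusted p = 0.153), Dlk1 (2.58, adjusted p = 0.319), Tshz2 (-1.17) and Ifit3b (-2.98), none of which passed. In progenitor-like cells Dlk1 (2.50) and Ifitm3 (-1.73), and in neuron-like cells Ifit1 (-4.03; -3.41 without DeltaSP 1), Isg15 (-3.87; -3.07 without KO 1, -5.72 without KO 2), Ifitm3 (-1.73) and Asphd2 (-0.81), did not pass. Genes named in every comparison lay between Chat at -0.34 and Mki67 at 0.49 in all cells, between Isl1 at -0.63 and Mki67 at 0.27 in progenitor-like cells, and between Chat at -0.04 and Olig2 at 0.56 in neuron-like cells. At an unadjusted p under 0.05 there were 817, 623 and 784 genes. The all-cell count was 4 without WT 1, 4 without WT 2, 4 without DeltaSP 2 and 2 without KO 2; in progenitor-like cells it was 4 without WT 1, 4 without WT 2, 3 without DeltaSP 2, and 0 without KO 1 or KO 2, where the targeted transcript did not pass. In neuron-like cells it was 2 without WT 1, 2 without WT 2 and 3 without DeltaSP 2.

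By camera 15 of 34 lists passed between KO and DeltaSP in all cells. Pluripotent, surface epithelium, S phase, G2 and M phase, p53, hypoxia, immediate early, cholesterol and Y chromosome genes were higher in KO. Pan-neuronal (adjusted p = 1.72e-05), mesoderm, synaptic, neurofilament, locus and ribosomal genes (adjusted p = 1.14e-21) were lower. In these lists 0 members passed edgeR but in the locus list, where 1 of 13 did, the targeted transcript itself. The lower call of the locus list therefore does not show a change of the neighbours. Over the list alone 0 members of these 15 lists passed outside the locus list, and 0 lists passed with an estimated correlation, where the lowest value was adjusted p = 0.472 with an estimated correlation and 1 list had an unadjusted p under 0.05. The number of lists was 3 without DeltaSP 1, the library that also lacked Y-linked transcripts. In progenitor-like and neuron-like cells 10 and 17 of 29 lists passed, the lowest values being adjusted p = 0.312 and adjusted p = 0.468 with an estimated correlation, and the locus list, lower in both, differed in sign between median and mean. In all cells the median, mean and test differed in sign for the interneuron, glial, Hox 6 to 10 and mitochondrial lists, which did not pass.

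The differences of KO and of DeltaSP from WT had the same sign in 85.2% of genes, against 67.3% in the simulated groups described next. Across 14872 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.859 and a covariance of 0.426, where groups simulated without any change against the same WT libraries gave 0.546 and 0.0777. With a different WT library for each comparison, r was 0.456 and 0.526, where the simulated groups gave 0.0016 and 0.0053. The simulation drew each gene independently, which by itself sets these simulated r near 0. Real unchanged clones that differ in cell mix or depth could give another r. The simulated groups therefore do not show that the edits share an effect. An ancestry that the DeltaSP and KO clones might share and WT lacks is not separated from the edits either. Of the genes that passed, 35 rose in both and 7 fell in both, in lists called against the same WT libraries.

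A separate test asked which changes differed between progenitor-like and neuron-like cells. Only Ptn, a secreted growth factor that binds heparin, passed among 13695 genes in edgeR: in KO its change was 0.51 in progenitor-like cells and -2.13 in neuron-like cells, and in DeltaSP 0.54 and -1.31. The clusters that made up the neuron-like class differed as well. A motor neuron-like cluster with little Ptn (26.4 plain CPM in WT, 20.3 in the edited libraries) held 0.534% of neuron-like cells in WT 1 and 22.4% in WT 2. It held 38.5% to 40.5% in each DeltaSP and KO library. Libraries were clustered without integration, and 52.05% of the neuron-like cells of WT 1 lay in a cluster it mostly filled. The value of WT 1 therefore does not separate cell mix from a split by library or depth. The count in KO was 114 without WT 1, 264 without WT 2, 5 without DeltaSP 1 and 6 without DeltaSP 2, and in DeltaSP 3 without WT 1, 198 without WT 2 and 3 without DeltaSP 1. At an unadjusted p under 0.05 there were 1681 genes for KO and 986 for DeltaSP.

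Mir325 lies within the span of the targeted transcript and Mir384 beside it, so genes with a matching site in the 3' UTR were compared with the rest. Sites of 8 bases for miR-325-3p, miR-384-5p and miR-466i-5p were tested in all cells and in both classes, for KO and DeltaSP against WT. The last was part of the plan, but its gene Mir466i is annotated on chromosome 13, away from the locus. By camera 0 of 18 tests passed, 0 had an unadjusted p under 0.05, and the lowest p was 0.0913. The median log2 fold change of genes with a site minus that of genes without was between -0.08 and -0.02 in every test, and control sites of matched composition gave medians of -0.0758 to -0.0264. For miR-325-3p in DeltaSP, 2, 4 and 1 of 100 control sites stood as high in all cells, progenitor-like and neuron-like cells, against 38, 48 and 10 in KO, a count without adjustment over the tests. With shorter sites included, 0 tests passed as well.

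**Figure D3:**
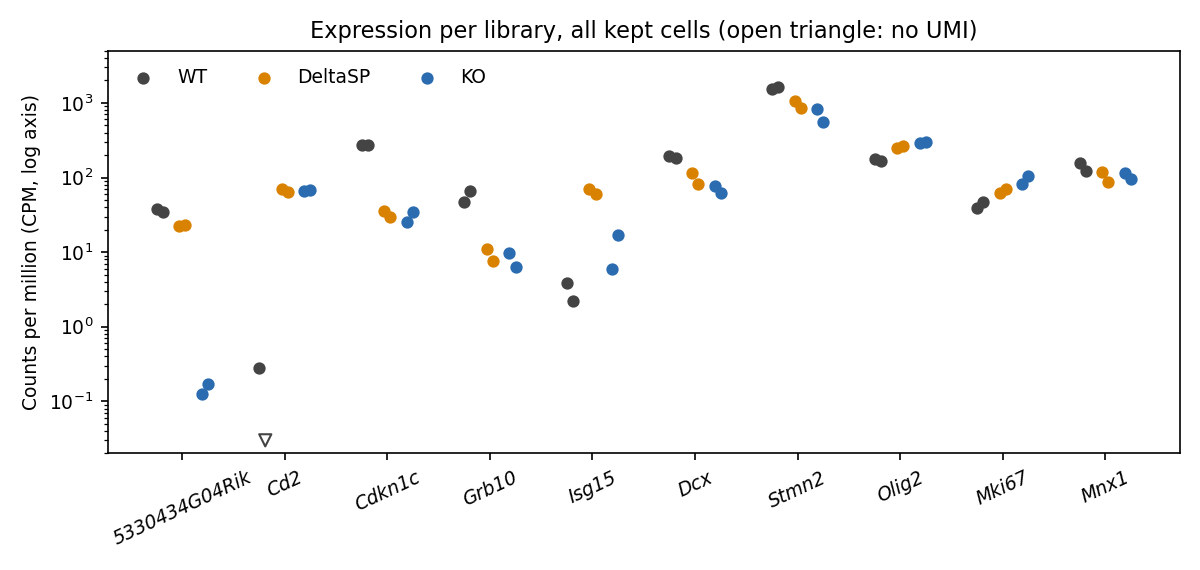
CPM (log axis, vertical) of 10 genes (horizontal axis) over all kept cells, with each library as a point and the open triangle marking a library with 0 UMIs. The targeted 5330434G04Rik lay at 0.125 and 0.172 CPM in KO, and Cd2 between 63.2 and 69.8 CPM in the DeltaSP and KO libraries.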

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

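The tests of cell shares, of free RNA, of the length bias in the shortest transcripts and of T lymphocyte genes above the WT level were chosen only after the result was seen. The values of Ptn by cell type and cluster, and the rho for Isl1, had no prediction written for them. The other tests in this part were written before the result, the DeltaSP test of the region around Cd2 once the KO value was known.

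Ptn, a secreted growth factor, differed between the classes of cells in its change against WT, and the test of that difference passed in edgeR. The effect in neuron-like cells minus that in progenitor-like cells was -2.69 ± 0.14 (SE, adjusted p = 0.000139) in KO and -1.87 ± 0.14 (adjusted p = 0.00281) in DeltaSP. With cells thinned to 3000 UMIs and those below left out (965 of 1218 motor neuron-like cells stayed in WT 1, 391 of 399 in KO 1), motor neuron-like cells with a Ptn UMI made up 25.3% and 29.3% in WT, 15.1% and 13.1% in DeltaSP and 11% and 6.34% in KO, against 1.52% and 0% of precursor-like cells in WT. Interneuron-like cells did not show this fall. Their share with a Ptn UMI was 9.846% and 5.66% in WT, the latter of 53 cells, and 21.37% and 19.18% in DeltaSP. In KO it was 8.602% and 21.05%, so the KO libraries disagreed. The lower Ptn of the neuron-like class was thus that of its motor neuron-like part. The clusters of the neuron-like class also differed: a motor neuron-like cluster with Ptn at 26.4 CPM in WT (here and below UMIs over the plain total) held 0.534% and 22.4% of neuron-like cells in WT and 38.5% to 40.5% in the other libraries. WT 1 clustered apart, with 52.05% of its neuron-like cells in a motor neuron-like cluster it mostly filled. Of the WT values, only the 22.4% of WT 2 bears on the mix of cells. In the 2 motor neuron-like clusters where Ptn was high it stood at 372 CPM in WT, where 878 cells were of WT 1 and 57 of WT 2, and at 759 CPM, where 3 and 204 were, against 146 and 344 CPM in the 4 DeltaSP and KO libraries pooled. The interneuron-like clusters went the other way, with Ptn at 455.9 and 29.19 CPM in WT and 688.8 and 48.7 CPM in the pooled libraries.

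KO libraries held fewer neuron-like cells than WT libraries. A difference in depth stays open. Thinning to 3000 UMIs left out 936 of 4496 cells of WT 1 and 56 to 201 of each other library. Without clusters the difference was then -19.7 percentage points, beyond the gap of 4.93 between the WT clones. With clusters it was -10.16, within their gap of 10.24. In that clustering 19.9% of WT 1 cells were unnamed, against 0.696% to 3.49% of each other library. The gap of 10.24 is therefore not separated from a difference in the cells left unnamed. The filter on genes per cell stays open. Barcodes below its minimum numbered 4788 of 9345 in WT 1, against 225 to 922 in each other library. Under the looser filter the difference was -7.46 points, below the gap of 8.55 between the DeltaSP clones. The lowest WT library still lay 3.38 points above the highest KO library. Under that filter 19.2% and 13.8% of WT cells were unnamed, against 5.33% to 8.16% of each DeltaSP and KO library. Unnamed cells count in the totals, so the smaller difference is not separated from the naming of clusters. Variation between clones stays open and cannot be told apart from an effect of the edit, because the edgeR test of cell counts did not pass (adjusted p = 0.083). An effect of the genotype on differentiation may be a cause and stays open beside it.

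Short transcripts were lower in KO than in WT. A bias with length between libraries that runs over all lengths is argued against: rho with length was at most 0.251 within a genotype, while in KO against WT it was 0.00524, and so the trend over all lengths left 2 further tests undecided (rho -0.00459 without ribosomal and mitochondrial genes, -0.013 in progenitor-like cells). In the shortest transcripts a bias between libraries is a candidate explanation, since WT 1 exceeded WT 2 there by a median of 0.24 without any difference in genotype. Ribosomal and mitochondrial genes were 70 of these 1476 genes, too few for their removal to move the median much. Without them the median was -0.37, so the lower level was also that of the other short transcripts. The median was -0.35 within progenitor-like and -0.32 within neuron-like cells, which argues against different shares of these classes alone. A different mix within a class stays open. In the progenitor-like class 1 cluster held 87.5% of the cells of WT 1 and at most 2.29% of those of any other library.

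Cd2, a T lymphocyte gene on chromosome 3 (101275899 to 101287939), was detected in both DeltaSP and both KO libraries and at 5 and 0 UMIs in WT. The test of T lymphocytes written beforehand was undecided. In the mutant libraries 16 of their genes summed to 0.285 to 0.348 of the Cd2 level, above the limit set for arguing against them. Most of that sum was Coro1a, at 16.8 to 26.3 CPM in every library. T lymphocytes are argued against by the later test, where the sum was at most -0.0285 of the Cd2 level once the WT level was taken off. Free RNA is argued against by a share of cells with a Cd2 UMI at least 13.8 times higher in motor neuron-like than in progenitor-like cells, and a change of the chromosome region by a median of 0.062 in KO and 0.078 in DeltaSP against WT over 11 genes. Cd2 followed Mnx1 over 19 clusters of the mutant libraries (rho 0.928), so a sequence controlled like Mnx1 in the mutant clones is a candidate source, which the labels do not name. With Isl1, another motor neuron factor, the rho was 0.677. Ranks over pooled clusters do not tell such a sequence from other expression in motor neuron-like cells. In the mutant libraries Cd2 ran from 10.8 to 415 CPM over the motor neuron-like clusters and from 7.49 to 69.3 CPM over the unnamed ones. If the mutant clones share an ancestry that WT lacks, that difference could not be separated from the edits in any comparison with WT.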

How the results depend on the processing

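The removal of the length trend, the highest doublet scores and the counting without clusters were chosen after seeing the data. For genes, the lists give changed counts in the order all cells, progenitor-like and neuron-like cells. Of 1434 values of the 88 named passing results under other settings, 1115 kept their call, 319 lost it and 0 reversed. Of 625 values of 39 results that did not pass, 522 stayed so, 83 passed and 20 reversed. All share differences kept their direction but not their size: with all libraries, KO minus WT ranged from -7.46 (looser filter) to -19.7 points (no clusters) for neuron-like and from -5.57 to -15.2 for motor neuron-like cells, and DeltaSP minus WT from -2.68 to -13.2 and from -0.997 to -10.7. In these neuron-like and motor neuron-like differences the looser filter gave the smallest, and libraries overlapped there except for neuron-like KO against WT. The edgeR test of cell counts gave 0 passing differences, the lowest at adjusted p = 0.083.

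Without a filter on low counts, KO against WT gave 3436, 1618 and 1705 genes, DeltaSP against WT 1369, 780 and 552, KO against DeltaSP 443, 380 and 252, and the test between classes 575 (KO) and 223 (DeltaSP). The DESeq2 Wald test gave 2397, 763 and 1067, then 606, 203 and 216, then 53, 21 and 44. The cause was not tested in either. With only the genotypes compared, which leaves fewer libraries, KO against WT gave 708 in all cells, DeltaSP against WT 14 and 13 in the classes, and KO against DeltaSP 4, 4 and 2. In progenitor-like cells the looser filter gave 293 for KO and 2 for DeltaSP against WT, resolution 1.2 gave 274 and the length trend removed gave 3 for KO, with 2435 genes at an unadjusted p under 0.05 against 2523. Without the highest doublet scores DeltaSP against WT gave 22, with 8 of the 14 named genes passing. With an estimated correlation 0 lists passed in each comparison. With a different WT library for each comparison the overlap had r of 0.456 and 0.526 (0.0016 and 0.0053 in groups simulated with independent genes). The cause was not tested for these.

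The replicate numbers do not pair the samples: the deviations of replicate 1 from replicate 2 correlated by -0.0167 (WT and DeltaSP), 0.138 (WT and KO) and 0.0253 (DeltaSP and KO). With the replicate block, DeltaSP against WT gave 22 in all cells, with 10 of the 14 named genes passing, and 6 in neuron-like cells. KO against WT gave 118 in progenitor-like cells. With the block and the length trend removed, DeltaSP against WT gave 3, 2 and 7, with 3 of the 14 genes named in all cells passing there. KO against DeltaSP gave 2 in each class. KO against WT gave 124 in progenitor-like cells, with 8 of the 12 named genes passing. The cause was not tested.

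Leaving out each library in turn, with the lone library of a genotype assumed to vary like the others, gave 4 to 3240, 0 to 2257 and 3 to 2020 genes for KO against WT, 1 to 1174, 0 to 1101 and 1 to 746 for DeltaSP against WT, and 1 to 4, 0 to 4 and 1 to 3 for KO against DeltaSP. Lists ranged from 8 to 15 (DeltaSP against WT) and 3 to 19 (KO against DeltaSP), and the test between classes from 1 to 264 (KO) and 1 to 198 (DeltaSP).

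Reversed values were all of genes that did not pass. Over the left-out libraries, Lhx3 in all cells ranged from -0.081 (without WT 2) to 0.24 in KO and from -0.048 (without DeltaSP 1; -0.028 without WT 2) to 0.29 in DeltaSP, and Neurog2 from -0.044 to 0.90 in KO and from -0.023 to 0.92 in DeltaSP, both lowest without WT 2. In neuron-like cells of KO, Mnx1 ranged from -0.13 (without KO 1) to 0.17, Isl1 from -0.37 to 0.18 (without WT 2), Chat from -0.17 (without WT 1; -0.14 without KO 2) to 0.26, and Tubb3 from -0.086 (without WT 1) to 0.33. With the length trend removed, and then with the block too, Lhx3 in all cells of KO was -0.025 and -0.011, Mnx1 in neuron-like cells -0.071 and -0.080, and Chat -0.062 and -0.059. At resolution 1.2 Mnx1 was -0.053 and Chat -0.16, and under the looser filter Isl1 was 0.053 and Chat -0.040. The cause was not tested. The simulated test recovered 48% to 59% of 2-fold changes. Depth was not varied there; summed counts thinned to the smallest library gave 1143 genes for KO and 56 for DeltaSP against WT.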

Other observations

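All tests and gene groups in this part were chosen only after the data were seen, except the Y chromosome list.

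Interferon-induced genes stood highest in the DeltaSP libraries. A group of 20 such genes summed to 111 and 140 CPM in WT (in this part UMIs over the plain library total), 827 and 638 in DeltaSP, and 206 and 370 in KO; 15 of them rose in DeltaSP and 14 in KO by edgeR. A cluster of progenitor-like cells led by Oasl2, Bst2, Ifit3 and Isg15 held 91 and 69 cells of the DeltaSP libraries, 3 and 15 of the KO libraries and 0 of the WT libraries.

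A cluster without a name, led by the germ cell genes Stra8 and Dazl, held 8 and 9 WT cells, 14 and 121 DeltaSP cells and 74 and 67 KO cells. The imprinted non-coding RNA H19 stood at 21.7 and 82.6 CPM in WT, 217 and 187 in DeltaSP, and 209 and 145 in KO, while its neighbour Igf2 stayed under 0.5 CPM in all 6 libraries. H19 led the mesoderm-like cluster, which held 1.58% and 2.01% of the WT cells, 3.68% and 4.09% of the DeltaSP cells and 3.21% and 1.63% of the KO cells, so a different share of that cluster is not separated from a change within cells.

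The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0.0853 CPM in DeltaSP 1 and to between 49.2 and 84.8 CPM in the other libraries; DeltaSP 1 held 0 UMIs of Ddx3y. Under the looser cell filter 27 cells of WT 1 carried neutrophil genes, at 5.40% of their UMIs against 0.00101% elsewhere in that library, and 7 of them passed the main filter. The other libraries had 0 cells in that cluster.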
